A study of Homo sapiens with 6 samples.

How the data were processed

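ATAC-seq was performed on 6 libraries of ARID1A-knockout Huh7 cells, 2 each of WT, V2084D and V2084D shSTUB1, and samples were grouped by their titles. Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2, SAMtools, Picard, MACS2, bedtools and deepTools and the build was hg38. Versions, settings and any shift of reads to the transposase cut site are not given in the sources used here. The deposited files are MACS2 narrowPeak lists, 1 per library, so peaks were called per sample and not on pooled samples, and long peaks carry several summits. The deposited score of each peak is the whole part of 10 times its −log10 q. The deposited fold (a ratio to local background), −log10 p and −log10 q are the authors' values for each peak, computed by their caller. The lowest deposited −log10 q in the 6 lists lay between 1.30 and 1.31. The fold and −log10 q of peaks were set side by side only within a list, since ranks from lists of different lengths show no change, while fold and −log10 p also served to recover reads, background and depth.

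Chromosomes 1 to 22 and X were kept, and the share of summits elsewhere was 2.07% to 2.60% per library. Peaks of all 6 libraries that overlapped by at least 1 bp were merged into 28879 regions, and a region counted as present in a library when a peak of that library overlapped it by 1 bp. Read totals were not used here. Depth was recovered by assuming MACS2's Poisson p-value and a fold of reads plus a pseudocount of 1 over background plus 1. That pair of equations gave a whole number of reads for 100% of the summits of each library within a tolerance of 0.001 in −log10 p. The lowest background of each library, 6.63, 6.54, 7.62, 11.1, 9.75 and 8.06 reads per 10000 bp in the order WT, V2084D, V2084D shSTUB1, then gave the relative depth. Summits rested on few reads, with medians of 8 to 12 per library, so a missing peak means that none was called at this depth and not that the region was closed.

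Genes came from a RefSeq table of the same assembly (GRCh38), which gives gene starts and ends but no strand, transcripts or exons. A promoter could therefore not be told from the other end of a gene. The planned promoter window was replaced by windows within 1000 bp of either end of a protein-coding gene, and the nearest start site by the nearest protein-coding gene within 50 kb. Whether a peak was exonic or intronic was not determined. No genome sequence was used here, so the planned search for 17 motifs and its GC correction were not run. Of 513 symbols in the 23 gene lists, 512 matched the table.

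For each pair of groups, regions and genes with a peak in both libraries of one group and in neither of the other were counted. Their expectation with no group effect kept each region's number of peaks and reassigned them to libraries with weights fitted to the list lengths (1000 draws, fixed seed). These draws treat regions as independent, and the same counts for crossed splits of the libraries served as a reference. On simulated lists, 19 to 20 of 20 simulations without an effect fell inside the 95% range for each comparison. The simulated lists came from the same fitted weights as the draws, so this checks the computation and not the ranges on real lists. With 200 seeded regions among 28879, the excess recovered averaged 95.8% for WT against V2084D in the WT direction and 56.9% in the V2084D direction, since the fitted weights absorb part of a gain. It averaged 83.0% and 87.1% for V2084D and shSTUB1 against each other, 93.4% for WT and 55.7% for shSTUB1 in the last comparison. Whole reads were recovered for 100% of 5000 simulated summits.

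Shares at gene ends, gene list counts and presence after knockdown were tested with Fisher's exact test, two-sided, with regions or genes as the unit, which are not replicates. List tests used as background the genes with a gene-end peak in 2 or more of the 4 libraries, with Benjamini-Hochberg adjustment over 138 tests. Similarity used the Jaccard index with an exact permutation over 15 splits. The named genes were, per comparison and direction, the 10 with the highest mean percentile of −log10 q within the lists that held the peak, up to 4 members of each fixed list by the same ranking, ARID1A and STUB1, and the first 3 regions outside gene ends. A few genes that met this rule are not reported here. A gene's peaks in both libraries need not overlap, as either gene end counts, and the printed folds are those of the strongest gene-end peak of each library. Intervals of shares cover counting error only. The lists, the tests, this rule and most alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 5, lists of equal length (7234 summits), 50% coverage of a region, windows of 200 bp at summits, gene-end windows of 500 and 2000 bp, the nearest gene, each library left out, and a replicate block. Thinning of reads to the lowest depth, an expectation given each gene's number of libraries, and the chromosome checks were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.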

Results

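Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in Huh7 cells, an established human hepatocellular carcinoma line. The cells lacked endogenous ARID1A, a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex, and carried a lentiviral Flag-tagged copy of either wild-type ARID1A (WT) or ARID1A with the missense change V2084D in the C-terminal part of the protein. Another group carried V2084D together with a short hairpin against STUB1, a ubiquitin ligase that works with the HSP70 and HSP90 chaperones (V2084D shSTUB1). Each of the 3 groups had 2 libraries, and the data are 1 list of accessible regions (peaks) per library. The series title places the experiment in a study of how ARID1A C-terminal missense changes are regulated and what they do in cancer. Nothing in the labels states that replicates came from separate cultures, so any p-value measures only the spread between these libraries or regions.

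The V2084D lists differed more in length from each other than any group differed from another on average. The WT libraries held 10441 and 7401 summits, the V2084D libraries 9231 and 30768, and the V2084D shSTUB1 libraries 21728 and 15326. On chromosomes 1 to 22 and X these formed 8861 and 6394 merged regions in WT (7628 ± 1744, SD, n = 2), 8008 and 22215 in V2084D (15112 ± 10046, SD, n = 2) and 16687 and 12320 in V2084D shSTUB1 (14504 ± 3088, SD, n = 2). An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so no p-value was attached to these totals. Sequencing depth, recovered from the deposited fold and p of each summit and expressed relative to the lowest library, was 1.01 and 1 in WT, 1.17 and 1.70 in V2084D, and 1.49 and 1.23 in V2084D shSTUB1. V2084D replicate 2 was therefore both the deepest library and the longest list, and V2084D replicate 1 held fewer regions than WT replicate 1.

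**Figure D1:**
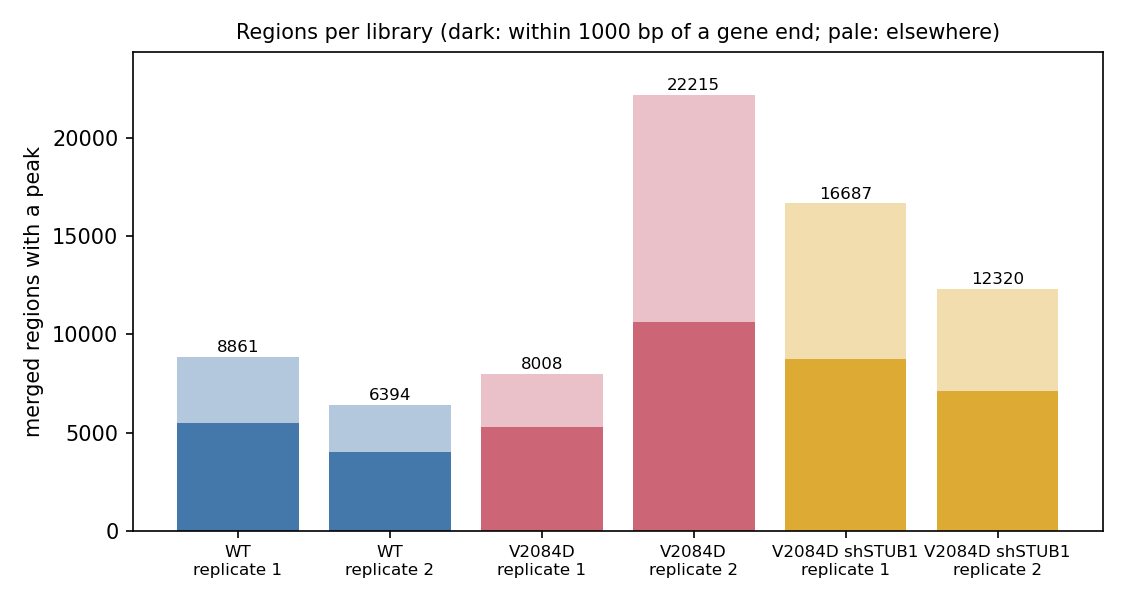
Bars give the number of merged regions with a peak in each library, with regions within 1000 bp of either end of a protein-coding gene in the dark part and all others in the pale part. The 2 V2084D libraries, at 8008 and 22215 regions, differed more than the libraries of either other group.

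Across the 6 libraries there were 28879 merged regions, of which 3269 had a peak in every library and 12791 in 1 library alone. Regions shared by all 6 libraries lay within 1000 bp of a protein-coding gene end in 76.8% of cases, against 24.1% of the regions seen in 1 library. The share at gene ends was 62.1% and 62.9% in the WT lists, 66.2% and 47.8% in the V2084D lists, and 52.4% and 57.7% in the V2084D shSTUB1 lists. Of 19974 protein-coding genes, 3243 had a gene-end peak in all 6 libraries and 8356 in none.

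The engineered genes were examined first. ARID1A (GRCh38, chromosome 1, 26696015 to 26782104) carried 1 peak in each of 3 libraries and none in the other 3. In WT replicate 1 the peak covered 26698091 to 26698290 with a fold of 3.76 over local background, and in WT replicate 2 it covered 26723117 to 26723417 with a fold of 5.08. In V2084D shSTUB1 replicate 2 it covered 26695514 to 26695730, with a summit 343 bp outside the annotated gene and a fold of 5.80. STUB1 (chromosome 16, 680410 to 682801) had no listed peak within 1000 bp in any of the 6 libraries. Peaks at these genes therefore check neither the knockout nor the knockdown, since a hairpin acts on the transcript and the edited position in ARID1A is not given in the sources used here.

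The comparison of WT with V2084D asks which accessible regions differ when the C-terminal missense form replaces wild-type ARID1A. A gene-end peak in both V2084D libraries and in neither WT library was found for 1015 genes, and the opposite for 11 genes. With no group effect and the observed list lengths, 873 (central 95% of draws 826 to 925) and 9.93 genes (4 to 16) were expected. The V2084D-only gene count thus exceeded its range and the WT-only gene count did not. These ranges treat genes as independent. The peaks of both libraries overlapped at 936 of the 1015 and 9 of the 11, and lay apart at the rest. Among the strongest V2084D-only gene-end peaks was that at RAB40C, a Rab-family GTPase gene (folds 8.08 and 8.80 in replicates 1 and 2, chromosome 16, 589184 to 589956 in replicate 2). Others lay at ZNF70 (8.91 in replicate 1), the shared peak of the mitochondrial ribosomal protein genes MRPL46 and MRPS11 (8.24 and 9.23), the Golgi GTPase gene ARL1 (8.64 and 8.53), SGSM3 (7.69 and 9.30), AARSD1 (7.87 and 8.85) and the actin-capping gene CAPG (7.35 and 8.18). All of these genes also had a gene-end peak in both V2084D shSTUB1 libraries, whose overlap with the V2084D peak was not determined. The 11 WT-only genes were led by the ribosomal protein gene RPL23A (folds 5.31 and 7.07 in replicates 1 and 2, chromosome 17, 28719584 to 28719917 in replicate 1), NUFIP2 (6.63 and 5.15), the isocitrate dehydrogenase subunit gene IDH3B (5.77 and 5.41) and the spliceosomal helicase gene DHX15 (3.85 and 6.02). FIGLA, MAP3K6 and the neighbours DXO and WHR1, which share 1 peak of 4 reads at the summit in each WT library, followed. At the transporter gene ABCB6 and at ETAA1, an activator of the ATR kinase, the peaks of the WT libraries did not overlap and lay 257 and 25 bp apart.

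Members of the gene lists fixed beforehand were spread thinly among the V2084D-only genes. The TGF-beta pathway list had 4 of its 10 testable members there, among them the receptor gene TGFBR2 (folds 4.94 and 5.19), SMAD4 (3.97 and 5.95) and ID2 (4.20 and 3.05). The list of YAP and TEAD targets had 3 of 9 (PTPN14, CCN2 and F3), and the cytosolic ribosomal proteins 3 of 22 (RPLP1, RPS2 and RPL30). SWI/SNF subunits contributed 2 of 12, SMARCC2 (4.88 and 6.10) and SMARCD2 (4.74 and 5.32), and the chaperones and STUB1 partners 2 of 19, the HSP70 co-chaperone genes BAG3 and BAG5. Single members came from AP-1 factors (JUND), epithelial and mesenchymal markers (TWIST1), both with peaks that did not overlap between the libraries, Wnt and beta-catenin targets (CTNNB1, folds 5.56 and 8.80), hepatocyte metabolism (ASL, a urea cycle enzyme gene), the cell cycle (CDKN1B), p53 targets (TNFRSF10B), the DNA damage response (XRCC5) and the proteasome (PSMC1). No member came from hepatocyte transcription factors, hepatocyte secreted proteins, cholesterol and lipid synthesis, PI3K and AKT, the interferon response, the unfolded protein response, or leukocyte, endothelial, fibroblast and stellate, or neuronal markers, and no list had a member among the WT-only genes. The TGF-beta count had an unadjusted p of 0.0254 by Fisher's exact test and an adjusted p of 0.585 over the 138 tests of 23 lists in 6 directions, so it did not pass. Over all 138 tests none passed an adjusted p of 0.05, with a smallest adjusted p of 0.509, and 7 had an unadjusted p under 0.05 by Fisher's exact test, where the counts these tests can take give 2.67 by chance. That comparison takes no account of how often each gene had a peak in any group. With each gene's number of libraries taken into account, 2 tests had an unadjusted p under 0.05 and none passed.

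**Figure D2:**
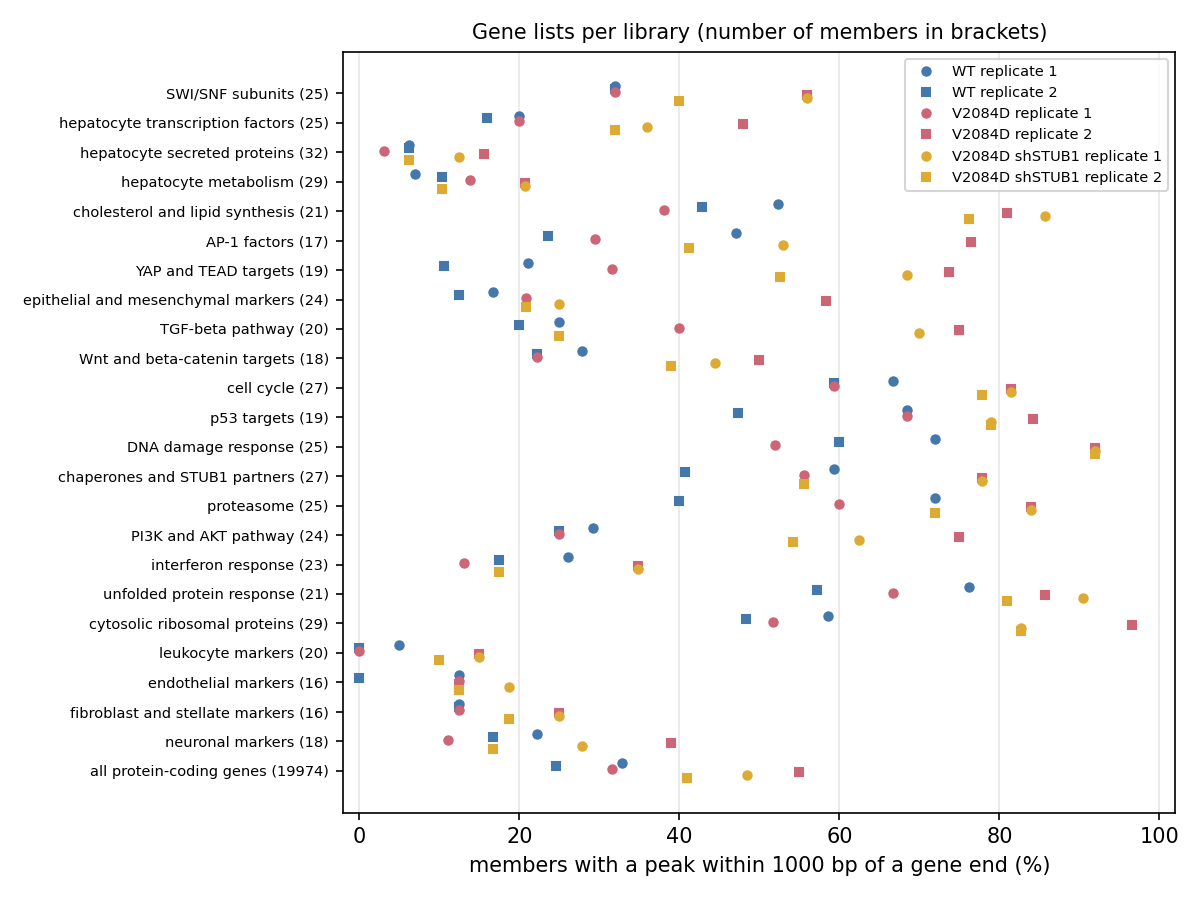
Each row is a gene list fixed beforehand, and each point the percentage of its members with a gene-end peak in 1 library, with circles for replicate 1 and squares for replicate 2. The bottom row gives all 19974 protein-coding genes, where V2084D replicate 2 had 10970 and WT replicate 2 had 4897 genes with a peak.

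By regions, 1606 had a peak in both V2084D libraries and neither WT library, and 54 the reverse. With no group effect and the observed list lengths, 1388 (central 95% of draws 1321 to 1450) and 51.9 were expected. The V2084D-only count thus exceeded its expectation by a ratio of 1.16, and the WT-only count of the deposited lists did not leave its range. WT-only regions did exceed their range with windows of 200 bp at summits (153, range 94 to 135), with reads thinned to the lowest depth (167, range 107 to 153) and at equal length. With a −log10 q of at least 5 they did not (21 against 21.2 expected). V2084D-only regions exceeded their range in each of these settings. They numbered 2179 with windows of 200 bp (range 1866 to 2022), 1160 with thinned reads (945 to 1061) and 801 with the stricter q (595 to 688). Outside gene ends, the leading V2084D-only regions were on chromosome 1 from 39606206 to 39606782, which lay 16652 bp from HEYL (folds 7.98 and 10.7), and on chromosome X from 115885296 to 115885905, with no protein-coding gene within 50 kb (3.91 and 4.44). They were followed by a region on chromosome 15 from 68229297 to 68230211 inside CLN6 (6.50 and 8.06). The leading WT-only regions lay inside TBCD (chromosome 17, 82754685 to 82755163) and inside ASPH (chromosome 8, 61689727 to 61690273, folds 6.49 and 6.06). Gene ends made up 31.5% of the WT-only and 57.6% of the V2084D-only regions (odds ratio 0.338, two-sided p = 2.1e-04 by Fisher's exact test, with regions as the unit). When every list was cut to 7234 summits, 507 regions were WT-only and 476 V2084D-only (436 and 345 expected with no group effect, ranges 398 to 476 and 311 to 379), and 258 of the 1015 V2084D-only genes and 4 of the 11 WT-only genes kept their pattern. Without V2084D replicate 2 the gene-end odds ratio reversed to 1.36, and without V2084D replicate 1 it was 0.817.

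**Figure D3:**
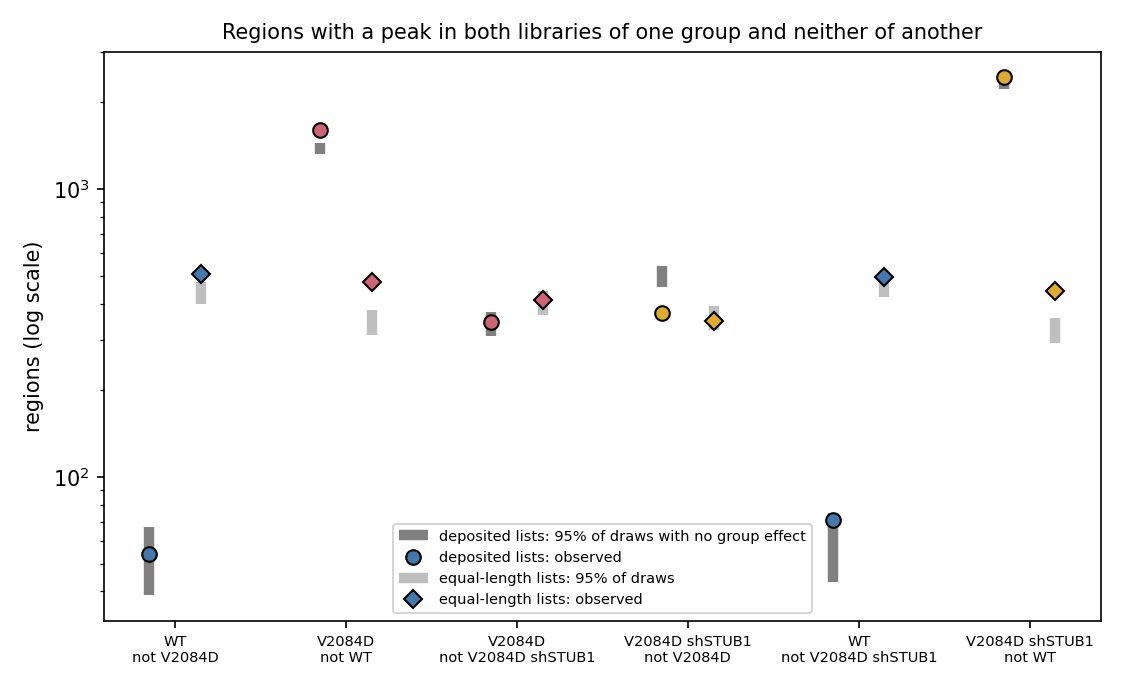
Points give the number of regions with a peak in both libraries of one group and in neither of another, on a log axis, for the deposited lists (circles) and for lists of 7234 summits each (diamonds). Grey bars span the central 95% of 1000 draws with no group effect, and the deposited counts of 54 and 1606 for WT against V2084D become 507 and 476 at equal length.

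The comparison of V2084D with V2084D shSTUB1 asks what a hairpin against STUB1 changes in cells with the missense form. The titles name no control hairpin for the V2084D group, so lowering STUB1 cannot be told apart from carrying a hairpin. Gene-end peaks in both V2084D and neither shSTUB1 library marked 135 genes (overlapping peaks at 113), led by REEP4, an endoplasmic reticulum shaping gene (folds 7.34 and 5.86, chromosome 8, 22141771 to 22142152 in replicate 2), the ubiquitin ligase gene TRIM33 (6.74 and 6.20), the lysyl oxidase-like gene LOXL1 (5.31 and 6.91), STYK1 (6.43 and 7.14) and SPOCK3 (6.62 and 6.13). RPS2, TTC7A, POPDC3 and the neighbours CIAPIN1 and COQ9 (1 shared peak, 5.65 and 7.41) completed the leading 10. REEP4 and the TGF-beta signal transducer gene SMAD2 had a gene-end peak in both WT libraries as well, so they were without one in the knockdown libraries alone. In the opposite direction 69 genes qualified, with overlapping peaks at 54, among them the peroxisomal protease gene LONP2 (folds 7.79 and 5.56), the cotransporter gene SLC12A4 (5.29 and 7.35), ZNF223 (5.47 and 6.62), PAK5, CNIH1 and RASA4B, a member of a set of near-identical copies. The first-ranked gene of this direction, the splicing factor gene U2AF1L4, had peaks 165 bp apart. Those at DNAJC8, SH3D19 and the retinaldehyde dehydrogenase gene ALDH1A2 did not overlap either. With no group effect, 110 V2084D-only genes (central 95% of draws 91 to 131) and 105 shSTUB1-only genes (86 to 125) were expected. The 135 genes thus lay just above their central range, though not outside the draws. The 69 lay below theirs and outside the draws.

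Among the fixed lists, the V2084D-only genes held 2 of 11 testable AP-1 factors, JDP2 (folds 5.38 and 5.95) and JUND, whose peaks lay 1926 bp apart in the libraries, with an unadjusted p of 0.00915 by Fisher's exact test and an adjusted p of 0.509. They also held 2 of 14 TGF-beta pathway genes, SMAD2 (5.49 and 5.43) and ID2 (unadjusted p 0.0147 by Fisher's exact test, adjusted p 0.509), TWIST1 and RPS2. The shSTUB1-only genes held 1 list member, the ribosomal protein gene RPL11 (folds of 6 and 5 in replicates 1 and 2). None of these counts passed.

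By regions, 345 had a peak in both V2084D and neither shSTUB1 library, against 342 expected with no group effect. The reverse held for 372 regions, fewer than the 498 expected (455 to 541), and this shortfall was not kept at equal length (349 against 357 expected), with thinned reads (573, range 563 to 656) or with windows of 200 bp at summits (803, range 785 to 892). It was kept with a −log10 q of at least 5 (172 against 227 expected, 198 to 255). V2084D-only regions exceeded their range in that setting (203, range 127 to 171) and by little with windows of 200 bp (718, range 615 to 712). The leading shSTUB1-only region outside gene ends lay inside GRK5 (chromosome 10, 119315593 to 119315845, folds 9.21 and 6.59), and the leading V2084D-only regions lay inside ZNF511-PRAP1 (chromosome 10, 133318514 to 133319008) and KDELR1 (chromosome 19, 48391282 to 48391772). Gene ends made up 42.6% of V2084D-only and 28.0% of shSTUB1-only regions (odds ratio 1.91, two-sided p = 4.5e-05 by Fisher's exact test over regions). That ratio was 0.957 without V2084D replicate 1 and 0.459 without V2084D replicate 2. Only 4 of the 135 and 1 of the 69 genes kept their pattern at equal length, among them LOXL1 and TTC7A, and U2AF1L4 with its separate peaks.

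The comparison of WT with V2084D shSTUB1 asks how far the knockdown cells stand from WT. A gene-end peak in both shSTUB1 and neither WT library was found for 1398 genes (overlapping peaks at 1239), led by the shared peak of GTF3C1, a TFIIIC subunit gene, and KATNIP (folds 11.9 and 9.28, chromosome 16, 27549607 to 27550273 in replicate 1), the homeobox gene DLX4 (9.44 and 10.6), the mitochondrial ribosomal protein gene MRPL42 (8.91 and 9.15) and SMIM13 (8.18 and 8.91). SPOUT1, the mitotic kinesin gene KIF23 and the augmin subunit gene HAUS4 followed. The reverse pattern held for 24 genes (overlapping peaks at 20), led by GOLGA6A, a member of a family of near-identical copies (7.33 and 6.17), the shared peak of the chaperone gene DNAJB11 and TBCCD1 (7.53 and 5.23), the autophagy gene ATG16L1 (5.70 and 6.16), TRIM66 and the NDRG4 and SETD6 peak. KIF5B, SESN3 and, with its separate peaks, ABCB6 followed. With no group effect, 1355 shSTUB1-only genes (central 95% of draws 1300 to 1411) and 16.2 WT-only genes (9 to 24) were expected. Neither gene count left its range, although the 24 lay at its upper limit.

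YAP and TEAD targets had 6 of 11 testable members among the shSTUB1-only genes, the named ones being FJX1 (folds 3.67 and 6.36), LATS2 (5.06 and 5.36), AXL and CCN1, with an unadjusted p of 0.00408 by Fisher's exact test and an adjusted p of 0.509. The AXL peaks of the libraries lay 43295 bp apart, and those at CCN1 did not overlap either. The expectation given each gene's number of libraries was 4.74 members. PI3K and AKT pathway genes had 5 of 12, including RPTOR (6.88 and 5.77), AKT2, PIK3CB and PDPK1 (unadjusted p 0.0332 by Fisher's exact test, adjusted p 0.655), and cholesterol and lipid synthesis genes 5 of 16, including IDI1 (7.32 in replicate 2), LSS and, with peaks 387 bp apart, INSIG1. Cytosolic ribosomal proteins had 5 of 24, TGF-beta genes 3 of 9, DNA damage genes 3 of 23 and proteasome genes 3 of 21. Hepatocyte transcription factors contributed 2 of 7, CEBPD (5.61 and 6.76) and HNF4G (5.48 and 7.14), and the urea cycle gene CPS1 (6.25 and 7.25) was the hepatocyte metabolism member. The unfolded protein response had 2 of 18 (ASNS and, with separate peaks, ATF6), the cell cycle 2 of 22 (CDKN1B and, with separate peaks, CDKN2A), and the leukocyte list 1 of 2, SPI1 (7.07 and 5.68). On the WT side, GAP43, with peaks 70 bp apart, and SMAD2 were the list members, at unadjusted p values of 0.0111 and 0.0249 by Fisher's exact test for the neuronal and TGF-beta lists. None passed adjustment.

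By regions, 2442 had a peak in both shSTUB1 and neither WT library (2295 expected, 2219 to 2379), and 71 the reverse (59.0 expected). With a −log10 q of at least 5 the shSTUB1-only count fell inside its range (1462, 1364 to 1479) and the WT-only count left its own (46, 21 to 42), as it did with windows of 200 bp at summits (161, 113 to 157). The shSTUB1-only count exceeded its range with windows of 200 bp (3028, 2814 to 2996), with thinned reads (1649, 1473 to 1609) and at equal length. The leading shSTUB1-only regions lay inside TBC1D24 (chromosome 16, 2501178 to 2501828, folds 9.35 and 8.24) and inside NAV2 (chromosome 11, 20112309 to 20112929). At equal length the counts were 442 and 495 (322 and 463 expected, ranges 291 to 356 and 423 to 503), and 230 of the 1398 and 11 of the 24 genes kept their pattern. Gene ends made up 51.9% of shSTUB1-only and 33.8% of WT-only regions (odds ratio 0.473 for WT, two-sided p = 0.0036 by Fisher's exact test over regions), and the ratio was 1.37 without shSTUB1 replicate 1 and 1.07 without shSTUB1 replicate 2.

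Both comparisons were joined to ask whether regions lost in V2084D had a peak again after STUB1 knockdown. Of the 54 regions present in both WT and neither V2084D library, 14 had a peak in both shSTUB1 libraries (25.9%, exact Clopper-Pearson 95% interval 14.96 to 39.7%). Of the 1606 gained regions 776 did (48.3%, 45.8 to 50.8%), as did 1191 of the 2658 regions with a peak in exactly 1 library of each group (44.8%, 42.9 to 46.7%). The lost regions were thus less often present after knockdown than these mixed regions (odds ratio 0.431, two-sided p = 0.0055 by Fisher's exact test) or than the gained ones (0.374, p = 0.0013 by Fisher's exact test). Neither difference held throughout: lost against mixed was 0.787 at equal length, 0.850 with thinned reads and 0.911 with windows of 200 bp, and lost against gained was 0.751 and 0.863 in the last pair of settings, none past 0.05. At equal length, lost against gained was 0.571. Lost regions returned 14 times where 23.5 were expected with no group effect (14.98 to 34) and 0.696 from independent lists. Of the 1606 gained regions, 279 (17.4%) had no peak in either shSTUB1 library, where 244 were expected with no group effect (216 to 274) and 19.2 from independent lists. Among the mixed regions 499 of 2658 (18.8%) had none either, so the gained regions did not lack a peak more often than these. Both comparisons share the V2084D libraries on both sides. Without V2084D replicate 1 or 2, the lost-against-gained ratio reversed to 1.97 or 5.08.

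In the deposited lists, replicates of a group shared few more regions than libraries of different groups. The Jaccard index, the shared fraction of the combined regions, was 0.416 for the WT pair, 0.319 for the V2084D pair and 0.492 for the V2084D shSTUB1 pair. The 12 pairs across groups ranged from 0.254, between WT replicate 2 and V2084D replicate 2, to 0.5002, between V2084D replicate 2 and V2084D shSTUB1 replicate 1. Mean indices were 0.409 within and 0.395 between groups, a difference of 0.0133 that 6 of the 15 splits of the libraries into pairs equalled or exceeded (exact permutation p = 0.4, one-sided). The draws with no group effect gave 0.00738 (0.00444 to 0.0105), a range that treats regions as independent and so leaves out the spread between libraries. The smallest p these splits allow is 0.0667, which was reached with lists of equal length, where the difference was 0.0140 and only 1 of the 15 splits, the real one, was as large. The next split there gave 0.0133, so the real one led by little.

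Read density around the 3269 regions with a peak in every library was also compared by chromosome. On chromosome 6 the medians, on the log2 scale, were -0.20 and -0.12 in WT, 0.11 and 0.03 in V2084D, and 0.11 and 0.11 in V2084D shSTUB1. Chromosome 1 gave -0.15 and -0.09, 0.08 and 0.05, and 0.08 and 0.08 in the same order. Chromosomes 21, 11 and 17 went the other way, with differences of V2084D-carrying libraries from WT of -0.18, -0.14 and -0.13.

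**Figure D4:**
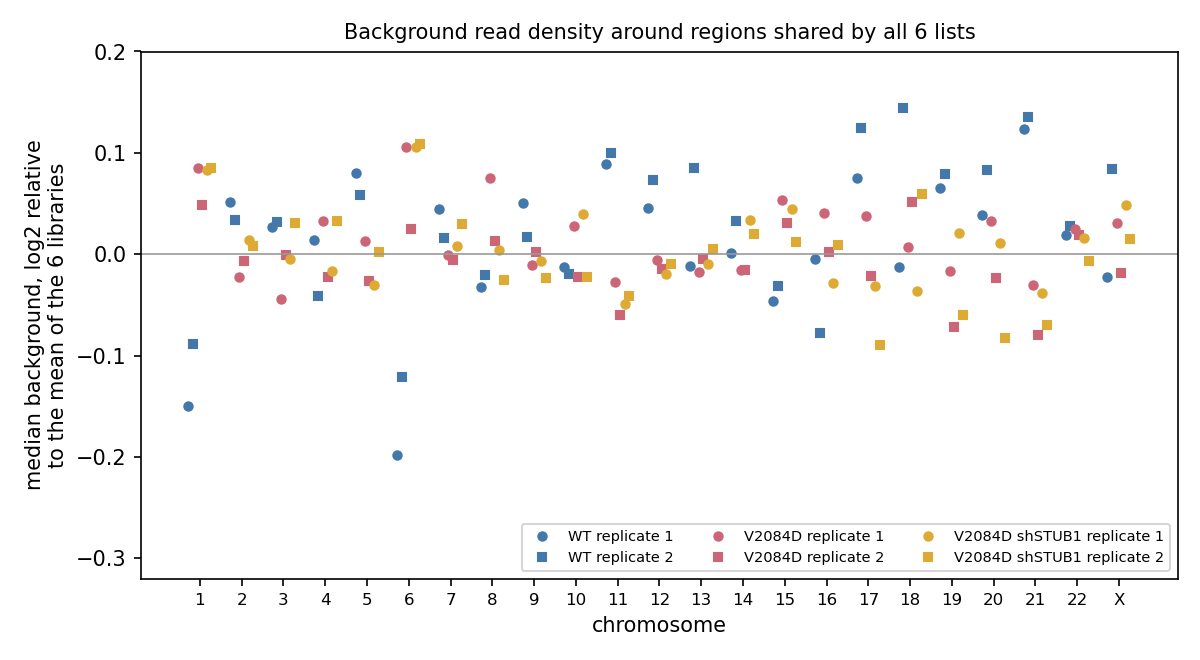
Points give each library's median background around shared regions by chromosome, on a log2 scale relative to the mean of the 6 libraries. The 2 WT libraries lay below the other 4 on chromosomes 1 and 6.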

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

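The pattern here was noticed while the data were explored, and the threshold of 0.2 (log2) and the test of depth or list length were chosen after seeing it, whereas the tests on gene-end against other regions were written down before they were run. Read density around shared peaks, outside the main measurement, was higher on chromosome 6 in the 4 V2084D-carrying libraries than in both WT libraries, by 0.25 on the log2 scale. The measure is the background within 10000 bp recovered at the 3269 regions common to all 6 lists, scaled by each library's median. It is taken at the summits of peaks, so reads of the peaks themselves can enter it. On chromosome 6 the medians were -0.20 and -0.12 in WT and 0.03 to 0.11 in the other 4, and on chromosome 1 the difference was 0.19, just under the threshold. With the lowest instead of the highest summit of a region, chromosomes 6 and 1 gave 0.25 and 0.19. The WT and the other libraries were fully separated on 12 of 23 chromosomes, with V2084D-carrying libraries higher on 3 (1, 6 and 15) and lower on the rest, and scaling by each library's median builds in part of such opposite shifts. The 2 WT libraries can be picked from 6 in 15 ways, so no p under 0.0667 was possible. In windows of 15 Mb with at least 20 shared regions, the largest rise was 0.38 on chromosome 1 between 30 and 45 Mb, while chromosome 1 showed none between 15 and 30 Mb (-0.01) or 105 and 120 Mb (-0.02). The largest difference of all was -0.49, at the start of chromosome 21 up to 15 Mb.

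A difference in depth or list length is argued against, though weakly and for chromosome 1 alone. The trend with either among the 4 V2084D-carrying libraries, carried to the WT libraries, gave an upper 95% limit of 0.0307 (log2) against 0.19 observed. That line rests on 4 libraries and was carried below their depths (1.17 to 1.70) to those of WT (1.01 and 1). No such trend was computed for chromosome 6. There V2084D replicate 2, the deepest library, lay at 0.03 and the other V2084D-carrying libraries at 0.11. A few regulated regions are argued against as well: the WT value was lower at 75.3% of the 369 gene-end regions and at 64.3% of the 112 other regions on chromosome 1, against 43.3% of regions on chromosomes other than 1 and 6. That 43.3% pools both kinds of region. Away from gene ends chromosome 1 stood out less: chromosomes 6, 8 and 15 gave 66.7%, 63.6% and 65.2%, and the rest 57.7% or less. A difference in DNA copy number between the lines remains a candidate explanation, but this measure cannot tell it from a difference in accessibility, since reads of peaks can enter it. It remains because the shift was present at both kinds of region, with medians 0.11 (log2) apart on chromosome 1 (0.22 and 0.11) and at 0.26 and 0.23 on chromosome 6. The limit of 0.15 for that test was lenient, as the shift at other regions on chromosome 1 was much smaller than at gene ends. Chromosome 21 does not share this feature: its fall was at other regions (-0.39), with gene ends at 0.06. An effect of the missense protein on these chromosomes, and GC content, were not tested, and genotype and cell line cannot be separated in this design.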

How the results depend on the processing

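Thinning of reads and the expectation given each gene's number of libraries were chosen after seeing the data, and the planned motif and GC alternatives were not run. Counts of regions and genes moved most, and most of that follows from how each alternative is built, since fewer summits or 1 library per group change what can be called; other causes were not tested. The count of gene lists past an adjusted p of 0.05 was 0 under each alternative run for it, which left out the settings without a library and the replicate block. No named gene or region changed direction, but most of these settings only remove peaks and so could not reverse one. Many lost their pattern. At equal length 4 of 10 WT-only and 14 of 32 V2084D-only named genes kept it, 2 of 15 V2084D-only and 1 of 11 shSTUB1-only, and 9 of 12 WT-only and 17 of 51 shSTUB1-only. With a −log10 q of at least 5 these were 0, 13, 5, 1, 0 and 18. Summits rested on medians of 8 to 12 reads, which limits calls near the threshold.

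With a −log10 q of at least 5, the summits were 3910, 2464, 2634, 16230, 10117 and 6300 in the order WT, V2084D, V2084D shSTUB1. WT-only and V2084D-only regions were then 21 and 801, V2084D-only and shSTUB1-only regions 203 and 172, and WT-only and shSTUB1-only regions 46 and 1462, with 37 WT-only genes in the last pair. The gene-end odds ratios lost their p, at 0.592 for WT against V2084D and 0.850 for WT against shSTUB1, as did lost against mixed regions (0.396) and lost against gained regions (0.419). At equal length, regions were 507 and 476 for WT and V2084D and 495 and 442 for WT and shSTUB1. Genes were 349 and 388, 337 and 253 (V2084D and shSTUB1), and 353 and 339, and lost against mixed was 0.787. Windows of 200 bp at summits gave 153 WT-only regions against V2084D, 718 and 803 between V2084D and shSTUB1, and 161 WT-only against shSTUB1, with lost against mixed at 0.911 and lost against gained at 0.863. Thinned to the lowest depth, WT-only counts against V2084D were 167 regions and 62 genes, shSTUB1-only against V2084D 573 and 228, and WT-only against shSTUB1 140 and 60, with lost against mixed at 0.850 and lost against gained at 0.751. With 50% coverage of a region, V2084D-only and shSTUB1-only genes were 211 and 118, and by nearest gene the latter were 109.

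Leaving out each library in turn loosens the criterion for the group left with 1 library, and none of these values has a test among libraries. WT-only against V2084D ranged from 61 to 1037 regions and 13 to 695 genes, and V2084D-only from 2171 to 12948 and 1097 to 3718. V2084D-only against shSTUB1 ranged from 616 to 7906 regions and 188 to 1206 genes, and shSTUB1-only from 428 to 3656 and 85 to 2141. WT-only against shSTUB1 ranged from 148 to 1046 regions and 55 to 196 genes, and shSTUB1-only from 3256 to 8047 and 1823 to 3159. Gene-end odds ratios ranged from 0.130 to 1.36 for WT against V2084D, reversed without V2084D replicate 2 (1.36). They ranged from 0.459 to 4.38 for V2084D against shSTUB1, reversed without V2084D replicate 1 (0.957) or 2 (0.459), and from 0.195 to 1.37 for WT against shSTUB1, reversed without shSTUB1 replicate 1 (1.37) or 2 (1.07). Lost against gained ranged from 0.0383 to 5.08, reversed without V2084D replicate 1 (1.97) or 2 (5.08). The within-group minus between-group Jaccard index ranged from -0.0245 to 0.0679, and was reversed without WT replicate 2 (-0.0219), shSTUB1 replicate 1 (-0.0245) or shSTUB1 replicate 2 (-0.0126).

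Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.0353, 0.0326 and -0.00748 over regions. With the replicate block, summed differences within numbers were 4278 and 19246 regions for WT and V2084D, 12890 and 11674 for V2084D and shSTUB1, and 2744 and 16496 for WT and shSTUB1. The numbers went opposite ways: 3671 WT-only and 2818 V2084D-only regions in replicate 1 but 607 and 16428 in replicate 2, and 1147 V2084D-only and 9826 shSTUB1-only in replicate 1 but 11743 and 1848 in replicate 2. Mantel-Haenszel odds ratios in the replicate block were 0.636, 1.38 and 0.582 at gene ends and 0.802 for lost against gained. The block counts need 1 library per group and so are larger by construction.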

Other observations

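Tests on the excess of V2084D-only regions and on regions lost in V2084D were chosen after those results were seen, whereas the tests of chromosomes 1 and 6 below were written down before they were run. In all 4 V2084D-carrying libraries and neither WT library, 608 genes had a gene-end peak, against 520 expected with no group effect (484 to 556). The reverse held for 5 genes, ABCB6, DXO, ETAA1, FIGLA and WHR1, against 0.85 expected (0 to 3), and these 5 were named after their values were seen. These ranges treat genes as independent, although DXO and WHR1 share 1 peak, and for regions crossed splits of libraries left their ranges too, so neither count shows an effect of genotype by itself. At ABCB6 and ETAA1 the peaks of the WT libraries did not overlap. Few markers of other cell types had a peak called: in the order WT, V2084D and V2084D shSTUB1, 1, 0, 0, 3, 3 and 2 of 20 leukocyte markers, 2, 0, 2, 2, 3 and 2 of 16 endothelial markers, 2, 2, 2, 4, 4 and 3 of 16 fibroblast and stellate markers, and 4, 3, 2, 7, 5 and 3 of 18 neuronal markers. Of 32 genes for proteins that hepatocytes secrete, between 1 and 5 had a gene-end peak per library, against 4897 to 10970 of all 19974 protein-coding genes.

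The excess of V2084D-only (1606) over WT-only (54) regions had 3 explanations under test. Depth alone is argued against, since thinning reads to the lowest depth left a ratio of 6.95 where the deposited lists gave 29.7. A gain of open regions in both V2084D cultures stays open: at matched depth V2084D replicate 1 had 0.846 times the regions of WT replicate 1 but 1.15 times those of WT replicate 2, and single libraries do not decide. Unequal list lengths stay open as well: they alone predict 1388 regions, the observed count was 1.16 times that, but a crossed split of the same libraries (WT replicate 1 with V2084D replicate 1) fell to 0.506 times its expectation, so the draws are too narrow to decide. Cutting the lists to 1 length brings the counts together largely by construction and decides nothing.

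The lower presence of lost regions after STUB1 knockdown may follow from their absence in the longest list. The 75 regions with a peak in 1 WT library and V2084D replicate 1 alone, which also lack one there, had a peak in both shSTUB1 libraries in 20% of cases, near the 25.9% of the lost regions (Fisher's exact test, two-sided p = 0.522). A WT-specific state that stays closed under knockdown would put the lost regions lower. They were 5.93 percentage points higher (Newcombe 95% interval -8.38 to 20.9), an interval that ends just short of a lowering of 10 points. It covers counting error over regions only, and the limit of 10 points was set after the result was seen. The test therefore cannot exclude such a state. Whether STUB1 knockdown restores WT accessibility stays open: 14 lost regions returned where 23.5 were expected, while 279 gained regions had no peak in either knockdown library where 244 were expected (216 to 274), and the draws behind both ranges are too narrow to decide. Against the mixed regions the gained ones showed no such excess, as 17.4% of the gained and 18.8% of the mixed regions had no peak in either knockdown library.

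A pair of consequences of the chromosome 1 and 6 difference were examined as hypotheses in lists of equal length. Chromosomes 1 and 6 held 95 of 476 V2084D-only regions (19.96%) and 62 of 507 WT-only regions (12.2%), against 16.7% of all regions (two-sided p of 0.00122 by Fisher's exact test between both sets of regions). The background difference may thus both add to the V2084D-only set, which includes the region near HEYL on chromosome 1, and take from the WT-only set, whose share departed more from that of all regions. Most of the within-group excess of the Jaccard index did not rest on these chromosomes, since 97.6% was kept without both (0.0137 of 0.0140). The real split then no longer led, as 2 rather than 1 of the 15 splits were as large and another gave 0.0140. Both chromosomes hold only 16.7% of all regions. Other chromosomes that separated the WT from the V2084D-carrying libraries stayed in. Whether background differences shape the similarity of replicates is therefore not decided.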
